A study of Arabidopsis thaliana with 18 samples.

How the data were processed

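The data are 18 Affymetrix ATH1 arrays of Arabidopsis thaliana Col-0, hybridised with biotin-labelled target made from total RNA, per the labels. The deposited values are intensities, one MAS5 signal per probe set on a linear scale; MAS5 is named in the submitters' processing notes and its version is not given in the sources used here. The mean of each array's deposited intensities, without the highest and lowest 2%, was 100.0, so the arrays had been scaled to a common mean, as judged from the values. No detection calls were used here. The table holds 22810 probe sets, of which 64 are controls, and all of its 18 columns were used. The profiles of any 2 of the 18 arrays, whatever their treatment, correlated between 0.831 and 0.978, so no array was counted as a copy of another.

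Arrays were grouped by the treatment and the replicate number in their titles. Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed. Values below an array's own 20th percentile were raised to it and log2 was taken. Control probe sets and probe sets with a mean log2 value under the 40th percentile were left out, which left 13652. Treatments were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust), with Benjamini-Hochberg adjustment and a threshold of 0.05, and replicate numbers and their interaction with treatment by limma's F test. A fold change is on this floored log2 scale, which understates the change of dim transcripts. Gene lists with at least 3 tested probe sets were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 6 lists tested, and again with an estimated correlation; where camera takes no such fit (the random block, and eBayes without trend), cameraPR was used on the fit's statistics. Single values per array were compared with an exact two-sided permutation test over all 48620 ways to choose 9 of 18 arrays, in Python 3.11.15.

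Probe sets were named by the platform annotation supplied, with symbols updated by gene identifier through an NCBI gene table of assembly TAIR10.1, used for names only, since the array's genome build is not given in the sources used here. Of the 22810 probe sets, 13513 name 1 gene, 503 name several and 8794 are unnamed here. Of the 13513, 13436 matched the gene table and 77 kept the annotation's symbol. Of the tested probe sets, 53.9% name 1 gene. The 17 gene lists were SA-inducible defence, SA biosynthesis and signalling, jasmonate and ethylene, endoplasmic reticulum folding, detoxification, receptor-like kinase, photosynthesis, clock, auxin, glucosinolate, tryptophan and camalexin, senescence, cold, drought and touch, heat shock, root, flower and seed, and reference genes. The rule named the probe sets with the largest changes past the threshold, of which there were none, up to 4 members of each list with the smallest p, and a few fixed genes. Genes outside the silwet range on 3 or more SA arrays, those with the smallest p and the autophagy genes were added after their values were seen. For 1 gene with several probe sets, the highest mean stood for it.

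The replicate numbers were checked for pairing. The mean deviations of the SA and silwet arrays with the same number correlated at 0.60, 0.56 and 0.63 for replicates 1, 2 and 3, and different numbers at -0.06 or below, so the numbers pair the arrays, from the data and not from a statement in the labels. The fit with the replicate number as a block is therefore given as an alternative, as is each value within a replicate number.

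The spread of each treatment was compared, after the data had been seen, with limma on each value's absolute deviation from its treatment mean, and by counting SA arrays at least 2-fold outside the range of all silwet arrays. The spread of the whole profile was compared by the ratio of summed squared deviations over all 48620 splits. The fits were tested on simulated data for 13652 probe sets with the means and spread of the silwet arrays. The level test called 93 of 100 probe sets raised 2-fold and 99 of 100 raised 4-fold on all SA arrays, and 9 of 13452 unchanged ones. The spread test called 5 of 100 raised 2-fold and 39 of 100 raised 4-fold on 3 SA arrays, and 3 of 13452 unchanged ones.

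The alternatives were no floor, log2 of the value plus 16, no filter or one at the 60th percentile, quantile normalization, median centring, eBayes without trend, array weights, the replicate number as a fixed or random block, 2 residual principal components as covariates, each array or replicate number left out, and 1 probe set per gene. A named gene's value was called moved where it shifted by over 1 SD. Leaving out 1 array cannot shift a mean that far. The replicate block, eBayes without trend and the 2 residual principal components cannot change a fold change in this balanced design. For these alternatives the bar is therefore no test of stability. For counts over many probe sets, 100 splits of the arrays, the real one included, were drawn with a fixed seed; the spread and range counts took the larger of both directions in each split.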

Results

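Transcript levels were measured in Arabidopsis thaliana plants of the reference accession Col-0 with the Affymetrix ATH1 array, a short-oligonucleotide array that represents each transcript by a set of probes (a probe set). Of the 18 arrays, 9 came from plants treated with 0.02% silwet, a surfactant that spreads a spray over the leaf, and 9 from plants treated with 0.30 mM SA (salicylic acid, a hormone of plant defence) in 0.02% silwet. The comparison asks which transcripts respond to SA beyond the surfactant. Each treatment has 3 arrays of each of the replicate numbers 1 to 3, and arrays are named here by treatment and by the number in their title, 1 to 9 for silwet and 10 to 18 for SA. The labels used here give no tissue and no time of harvest, so that all 9 arrays of a treatment were taken as one group. The study is known to have sampled plants at several times after treatment, so each group of 9 may mix times, and its means and SDs then cover them all. Nothing in the labels says that the arrays came from separate plantings, so p-values measure only the spread between these samples, which may be technical. The median signal of an array lay between 29.7 and 36.3, and the number of arrays limits the precision.

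The list of genes known to respond to SA was called higher as a set on the SA arrays only with a preset correlation. Its mean was highest on SA arrays 10, 11 and 12. Its mean log2 signal was 6.99 ± 1.56 (SD, n = 9) with SA and 6.19 ± 0.79 (SD, n = 9) with silwet, and limma's camera test with a preset correlation gave an adjusted p of 0.00238 for the higher direction. The correlation estimated between its genes was 0.839, and with it camera gave an adjusted p of 0.374. The exact two-sided permutation test of the list mean gave an adjusted p of 0.557. The list mean was 8.98, 8.95 and 9.12 on SA arrays 10, 11 and 12, and 6.31, 6.18, 6.53, 5.55, 5.42 and 5.88 on SA arrays 13 to 18. On silwet arrays 1 to 9 the list mean was 7.47, 6.75, 7.16, 6.04, 5.66, 6.35, 5.31, 5.62 and 5.34. Of the 9 SA arrays, 5 lay above the mean of all silwet arrays, which may span several harvest times. Since the silwet arrays differ this much, the 5 is not a count of the SA arrays on which the set rose. Of the 22 genes of this list, 5 could be named and tested, and none passed the test over all probe sets or adjusted over the list alone. UGT76B1, a glucosyltransferase that acts on the defence signal isoleucic acid and on SA, had a log2 signal of 7.12 ± 2.65 with SA and 4.73 ± 1.67 with silwet (SD, n = 9 each), a difference of 2.39 with a standard error of 0.95 (limma, adjusted p = 1.00). GRX480, a glutaredoxin that links SA to jasmonate responses, differed by 0.91 (standard error 0.49). The transcription factor genes WRKY53 and WRKY6 differed by 0.31 and 0.30, and SARD4, which acts in the synthesis of the defence signal pipecolic acid, by 0.10, with standard errors of 0.64, 0.36 and 0.39. The set's mean difference was 0.67, 0.84 and 0.89 within replicate numbers 1, 2 and 3. Camera with the preset correlation gave unadjusted p of 0.111, 0.00529 and 0.00257. Each replicate number holds 1 of SA arrays 10, 11 and 12, so these values are not support beyond those arrays. The call rested on single arrays. Camera gave an adjusted p of 0.0871 without SA array 10, 0.0927 without SA array 11 and 0.121 without SA array 12. With array weights the adjusted p was 0.742. The weights were 0.32, 0.31 and 0.33 for SA arrays 10, 11 and 12, against 0.73 to 3.06 for the other arrays. That fit thus plays down the arrays on which the list was highest and is no independent test of it. The log2 actin control ratio was 6.85 on SA array 10, 1.03 on SA array 11 and 0.45 on SA array 12.

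Of the other gene lists, 5 had at least 3 tested members and none was called by camera. GH3.3, which conjugates auxin to amino acids, had a log2 difference of 0.93 (standard error 0.35) and was the only tested member of the auxin list, with GH3.5 at 0.20 and IAA29 at -0.31, to pass adjusted over the list alone; over all probe sets, 0 of the 3 passed. The auxin list had an adjusted camera p of 0.236. The photosynthesis list, with LHCB4.1 at -0.10, LHCB4.2 at -0.11 and RCA at -0.06, also had an adjusted p of 0.236, and of 0.0288 (lower with SA) without SA array 18. The endoplasmic reticulum list (CNX2 at -0.0048, SEC61A at -0.06 and ERDJ3B at -0.10) had an adjusted camera p of 0.763. With array weights the adjusted camera p was 0.0326, lower with SA. The list mean was 9.56, 9.40 and 9.18 on SA arrays 10, 11 and 12, above every silwet array (8.51 to 9.04). On SA arrays 13 to 18 it was 8.27 to 8.65. The weights were lowest for SA arrays 10, 11 and 12, so the weighted call leans on the other SA arrays. The detoxification list (GSTU20 at 0.03, GSTU25 at 0.16 and UGT73B5 at -0.02) and the list of cold, drought and touch genes (COR15A at -0.05, COR47 at 0.02 and ZAT10 at 0.33) each had an adjusted p of 0.698. With an estimated correlation no list was called. No member of these 4 lists passed over all probe sets or adjusted over the list alone.

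A further 8 lists had 1 or 2 tested members, and no member passed over all probe sets or adjusted over the list alone. PDF1.2, a defensin gene induced by jasmonate and ethylene, had a log2 signal of 8.51 ± 1.69 with SA and 9.28 ± 1.70 with silwet (SD, n = 9 each), a difference of -0.77 with a standard error of 0.73. THI2.1, a thionin gene of the same list, differed by 0.16. SAG101, which acts with the SA signalling regulators of its list, differed by -0.02. The clock genes GI and COR27 differed by -0.16 and 0.06, the glucosinolate genes BCAT4 and UGT74B1 by -0.05 and 0.07, and the tryptophan gene IGPS by 0.03. The senescence list held SAG29, a sugar transporter gene, at 0.40, and WRKY53. The root marker PYK10 differed by -0.07, and the reference genes SAND and TIP41 by -0.09 and -0.01. The lists of receptor-like kinase, heat shock, and flower and seed genes had 0 tested members. PR1, PR2, PR5, ICS1, NPR1 and WRKY70 were not analysed here, since the probe annotation used names none of their probe sets.

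No single gene passed the test that takes the 9 arrays of each treatment as replicates of one group, whatever their harvest time. Of 13652 probe sets, 0 were higher and 0 lower with SA in limma at an adjusted p of 0.05, and 238 had an unadjusted p under 0.05, where 683 are expected by chance if no gene differs. Of these 238, 136 were higher and 102 lower with SA. A count below 683 is not evidence that no gene responds. Differences between arrays within a group of 9 count as replicate spread in this fit and can also lower it. With the first 2 principal components of the residuals as covariates, 2 probe sets unnamed here were higher with SA, by 1.14 and 0.61 (limma, adjusted p = 0.0180 and 0.0432). In that fit 827 probe sets had an unadjusted p under 0.05. The components were taken from the residuals of the treatment fit itself, so they leave each difference unchanged and act only on its error. The standard error of the difference of 0.61 was 0.155 without them and 0.100 with them. The 2 calls and the 827 may therefore be too many. The smallest unadjusted p among named genes, a selection made after the values were seen, belonged to petG, a chloroplast-encoded subunit of the cytochrome b6f complex, with a log2 difference of 1.63 ± 0.43 (standard error). ATG8H, an autophagy gene, differed by 0.69 ± 0.20 and was above the silwet mean on 8 of 9 SA arrays. AT2G41090, a calmodulin-like gene, differed by -0.35 ± 0.10, AT3G12510 by 0.74 ± 0.23, AT2G31945 by 0.73 ± 0.23 and AT3G06200 by -0.38 ± 0.12 (standard errors). On simulated data with the silwet arrays' spread, the same fit called 93 of 100 probe sets raised 2-fold on all 9 SA arrays, but 0 of 100 raised 4-fold on 3 of the 9. The simulation gave both treatments that spread and independent noise. In the data the median SD was 0.354 with SA and 0.281 with silwet, so the 93 may overstate what the fit can find here.

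**Figure D1:**
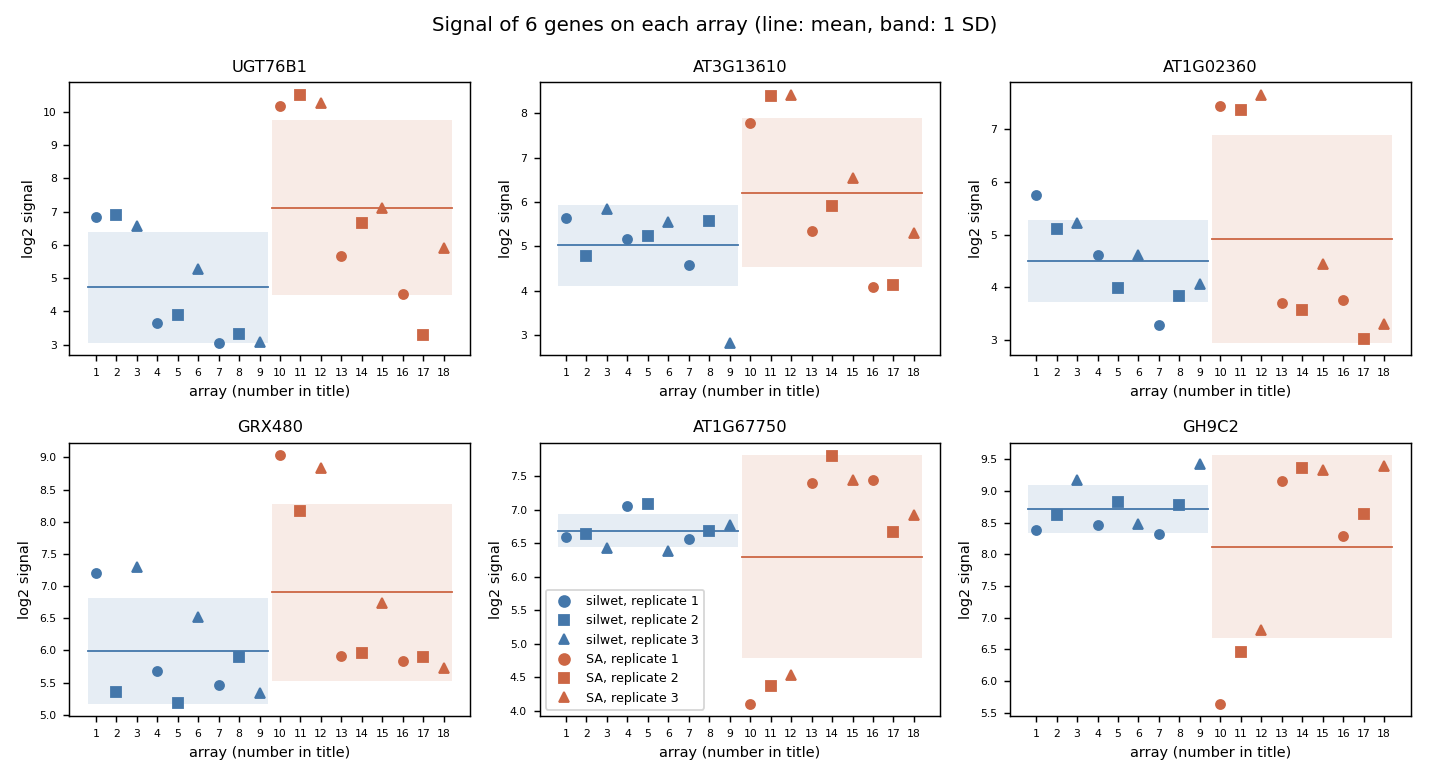
Log2 signal (vertical axes) of 6 genes on each of the 18 arrays (horizontal axes, the number in the array's title), with silwet arrays in blue and SA arrays in orange, the shape of a point giving its replicate number, lines the treatment means and bands 1 SD. UGT76B1, AT3G13610, AT1G02360 and GRX480 have their highest values, and AT1G67750 and GH9C2 their lowest, on SA arrays 10, 11 and 12.

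Single genes lay far outside the range of the silwet arrays on some SA arrays, a comparison chosen after the values were seen. UGT76B1 lay 5.44, 5.79 and 5.54 log2 units above the silwet mean on SA arrays 10, 11 and 12, and between -1.44 and 2.38 on the other 6 SA arrays. Among the silwet arrays it was highest on arrays 1, 2 and 3, at a log2 signal of 6.85, 6.89 and 6.57, against 3.06 to 5.29 on silwet arrays 4 to 9. WRKY53 (8.24, 7.61 and 6.93), AT4G01700 (7.78, 8.02 and 8.04) and AT3G02840 (5.96, 5.81 and 6.01) were also highest among silwet arrays on arrays 1, 2 and 3. On SA arrays 10, 11 and 12, AT3G13610 lay 2.74, 3.35 and 3.39 units above its silwet mean. It is listed with the synonym F6'H1, which makes the coumarin scopoletin. The chitinase gene AT1G02360 lay 2.95, 2.88 and 3.16 units above its silwet mean on the same SA arrays. SARD4 lay 1.48, 1.75 and 1.99 units above the silwet mean on SA arrays 10, 11 and 12 and -0.37, -0.62, -0.41, -0.88, -1.05 and -0.93 units from it on SA arrays 13 to 18. In the other direction, the pectate lyase genes AT1G67750 and AT4G24780 lay at -2.58 and -1.84 on SA array 10, at -2.32 and -1.49 on SA array 11, and at -2.15 and -1.48 on SA array 12. The endoglucanase gene GH9C2 lay at -3.07, -2.26 and -1.92 on these arrays.

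In all, 44 probe sets lay at least 2-fold above every silwet array on 3 or more SA arrays and 18 lay at least 2-fold below, of which 21 and 10 name 1 gene. The reverse count, silwet arrays outside the range of the SA arrays, was 0 above and 2 below. Of the 44 above, 42 were outside on exactly SA arrays 10, 11 and 12, as were 16 of the 18 below, so that the total of 62 falls by construction without any one of these arrays (4, 3 and 2 in turn), which is no test of its stability. It was 100 without silwet array 1. Among the 21 named genes above were a second chitinase gene (AT4G01700), the receptor kinase genes AT1G51890 and AT4G18250, the TIR-domain gene AT5G45000, SGT1A, which acts in resistance protein signalling, GFAT and ENGase85A. AT4G01700 lay 1.97, 2.19 and 1.99 units, and AT1G51890 1.95, 2.11 and 2.16 units, above the silwet mean on SA arrays 10, 11 and 12. Among the 10 below were the polygalacturonase gene AT1G10640 and the GDSL lipase gene AT1G29660, at -2.02, -1.74 and -2.62 and at -2.11, -2.93 and -2.35 on the same arrays. A limma test of the absolute deviations from the treatment mean called 403 probe sets, of which 5 were less variable among the SA arrays and the others more variable, 209 of these naming 1 gene. SARD4 (adjusted p = 0.0213), GFAT (0.0232), SGT1A (0.0476), AT1G67750 (0.0144) and GH9C2 (0.0284) were among those more variable, and UGT76B1 (0.665) was not. The count of more variable probe sets was 2116 with the replicate number as a block. That fit also called 84 probe sets less variable among the SA arrays. Its deviations, within sets of 3 arrays, are tied to each other but tested as independent, so the 2116 may overstate the difference. The count was 0 with deviations from the median and 0 without any one of SA arrays 10, 11 and 12. It was between 8 and 214 without any one of silwet arrays 1 to 6, 8 and 9, and between 714 and 805 without any one of SA arrays 13 to 18. The exact permutation test of the whole profile's spread (SA over silwet ratio 1.70) gave p = 0.0731. The log2 actin control ratio was 6.85 on SA array 10.

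**Figure D2:**
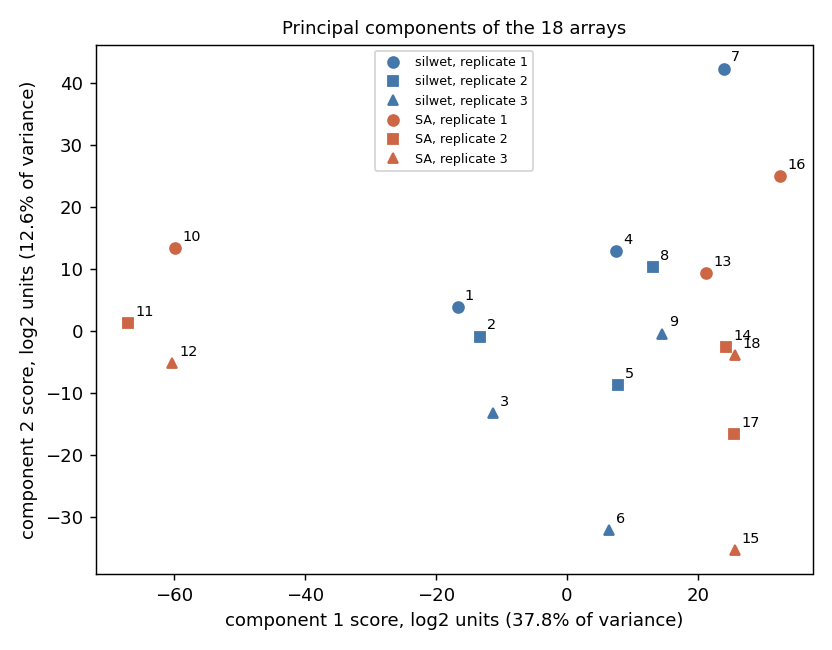
Scores of the 18 arrays on the first principal component (horizontal axis, log2 units, 37.8% of the variance) and the second (vertical axis, log2 units, 12.6%), each point an array with the number in its title, coloured by treatment and shaped by replicate number. SA arrays 10, 11 and 12 score -59.8, -67.0 and -60.3 on the first component, and the lowest silwet array, array 1, scores -16.7.

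Single chloroplast-encoded and nuclear transcripts differed between the replicate numbers. psbA, which encodes the D1 protein of photosystem II, was 2.70 log2 units higher in replicate 2 and 3.53 higher in replicate 3 than in replicate 1 (limma F test, adjusted p = 0.00502). petL, another cytochrome b6f subunit gene, was 1.53 and 1.68 units higher (adjusted p = 0.000817). Of the 66 chloroplast-encoded probe sets tested, 8 passed, and the group as a whole was not tested between replicate numbers. The mean log2 signal of the hybridisation spike controls was 7.79 to 8.13 in replicate 1 and 7.59 to 8.71 in replicate 2. In replicate 3 it was 8.57 to 8.99, apart from SA array 12 at 7.18. The spikes were not tested between replicate numbers, and a technical source of these differences cannot be told apart from others. SA array 10, with the log2 actin control ratio of 6.85, belongs to replicate 1, and psbA and accD lay at -4.43 and -4.51 log2 units from their silwet means on it. Without this array 13 passed, with psbA 3.03 units higher in replicate 3 than in replicate 1 (limma F test, adjusted p = 0.00202) and petL 1.62 units higher (0.00202). The count of 8 was 12 without SA array 12, 5 without any one of silwet arrays 1, 3, 4 and 9 and SA arrays 17 and 18, 4 without silwet array 2 or 5, 3 without 6 and 2 without 7. Nuclear genes passed too: the protein kinase gene AT3G28690 differed by -0.19 in replicate 2 and -1.07 in replicate 3 from replicate 1 (adjusted p = 0.000817), and AT1G47400 by 0.38 and -2.18 (adjusted p = 0.00307). In all, 97 probe sets differed between replicate numbers and 2148 had an unadjusted p under 0.05, and these genes were chosen after their values were seen. The count of 97 was 35 without silwet array 7, 39 without 6, 43 without 4, 53 without 9, 55 without 3, 62 without 5 and 64 without 2; it was 45 without SA array 16 and 62 without 18. The SA effect differed between replicate numbers for 0 probe sets, with 40 at an unadjusted p under 0.05 in the limma F test of the interaction.

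The mean of the chloroplast-encoded transcripts and the 5 prime signal of the actin control were low on SA array 10. The mean log2 signal of the 66 probe sets was 6.67 there, against 8.69 ± 0.31 (SD, n = 9) on the silwet arrays, with psbH at -5.32 and ycf4 at -5.12 log2 units from their silwet means. The 5 prime probe set of the actin control had a signal of 13.9 on this array and of 619 to 1318 on the other 17 arrays, while its 3 prime probe set had 1612. The log2 ratio of 3 prime over 5 prime was 6.85 on SA array 10, 1.03 on SA array 11 and 0.45 on SA array 12, and at most 1.43 on a silwet array. The GAPDH ratio was 3.36 on SA array 10 and at most 1.32 on the other SA arrays, whereas the ubiquitin ratio was 0.93 on SA array 10, below SA arrays 17 (1.06) and 18 (0.97). Between treatments the ratio was 1.43 ± 2.06 with SA and 0.69 ± 0.35 with silwet (SD, n = 9 each; exact permutation test, two-sided, p = 0.369). The GAPDH ratio (exact p = 0.424), the ubiquitin ratio (exact p = 0.734), the mean of the hybridisation spikes (exact p = 0.418), the array median (exact p = 0.580) and the chloroplast mean (exact p = 0.994) did not pass either, and the smallest adjusted p over the 12 quantities tested was 0.847.

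**Figure D3:**
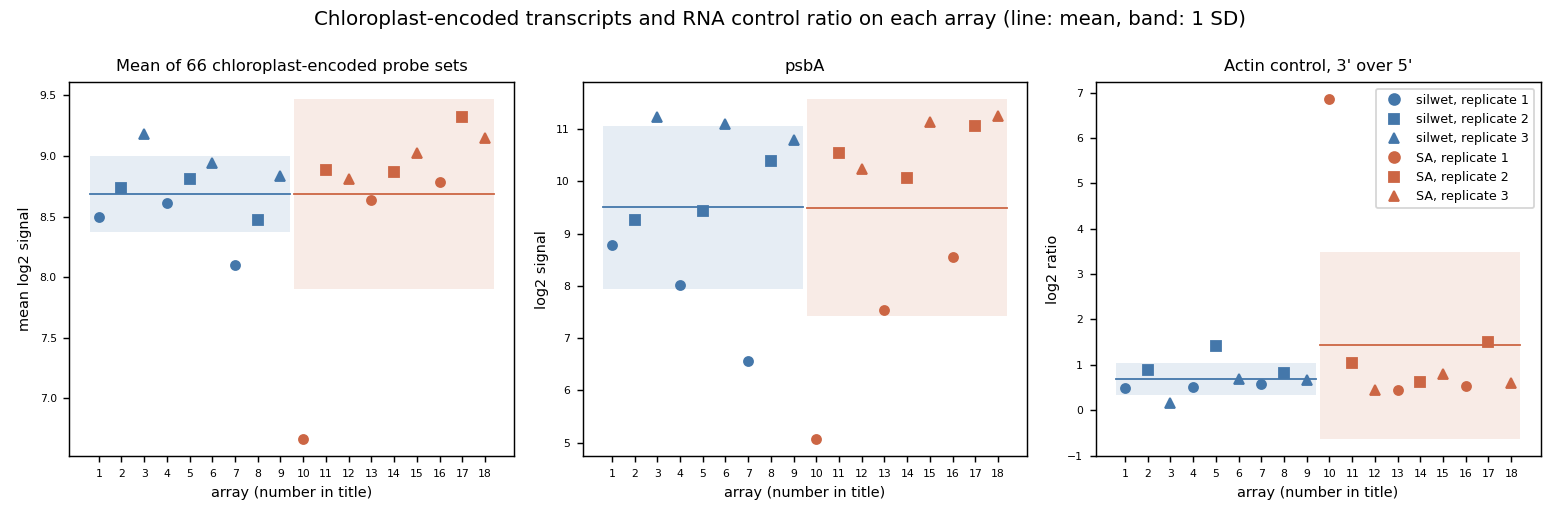
Mean log2 signal of the 66 chloroplast-encoded probe sets, log2 signal of psbA, and log2 ratio of the 3 prime over the 5 prime actin control probe set (vertical axes) on each array (horizontal axes, the number in its title), with treatments by colour, replicate numbers by shape, lines for treatment means and bands of 1 SD. SA array 10 stands lowest in the first 2 panels, at 6.67 and 5.07, and highest in the third, at 6.85.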

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

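The tests of array 10's chloroplast signal and of the RNA of arrays 11 and 12 were chosen after the results were seen, as were the spread counts themselves. The test of array 10 against the spread was fixed before its result was seen, and met what was foreseen for a cause, but it was judged undecided only after the result was seen, on the grounds given with it. Chance alone is expected to mark about 10 of the 202 groups of 9 values examined for one array far from the rest, and 16 were marked.

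On SA array 10 the chloroplast-encoded transcripts stood far below the other SA arrays, with a mean log2 signal of 6.67, and single transcripts did so too: psbH at 4.28, ycf4 at 4.71 and rbcL at 4.71. The log2 actin ratio of 6.85 and the log2 GAPDH ratio of 3.36 of the same array stood far above the others. Shortened RNA or target on this array cannot be told apart from other sources: its actin ratio exceeded the highest of the other 17 arrays by 5.35 log2 units, but its ubiquitin ratio of 0.93 lay below the 1.06 of SA array 17. The 3 tested probe sets of the nuclear photosynthesis list lay -0.21 log2 units from the silwet mean on array 10. For these 3, that argues against a fall as deep as that of the chloroplast-encoded mean. A smaller fall is not excluded: their mean was 11.17 on array 10 and at least 11.22 on the silwet arrays. It was lower still on SA arrays 11 (11.02) and 12 (11.09). After quantile normalization the mean was 11.30, 11.29 and 11.46 on SA arrays 10, 11 and 12. These values lay within the silwet range of 11.27 to 11.49, so the lower means depend on how the arrays are scaled. The other members of that list were not tested. Whether shortened RNA lowers chloroplast-encoded transcripts more than nuclear ones was not tested, and a biological explanation stays open for this 1 array.

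Of the 403 probe sets called, all but 5 were more variable among SA arrays. That count was reached by 2 of 100 splits of the arrays, the real one included, with 456 as the highest of the others. Among splits within replicate numbers, 3 of 100 reached it, with 718 as the highest. The spread was compared only after the data had been seen, so these shares do not exclude chance. The exact permutation test of the whole profile's spread gave p = 0.0731. Array scaling is argued against, since 348 probe sets were called after quantile normalization, 316 of them among those called without it. Shortened RNA on arrays 11 and 12 is argued against, since 0 of the 2 had an actin ratio above the highest silwet array. Degraded RNA on array 10 cannot be told apart as a contributor: without it the count was 0, but it was also 0 without array 11 or array 12. An effect of SA that differs with an unlabelled condition, such as time of harvest, may be the source and was not tested, since the labels do not give one.

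Among silwet arrays, AT5G02230 was high on array 7 (log2 signal 7.30), and AT4G18250 was low there (3.86). AT3G13610 was low on array 9 (2.83), and GI was low on array 6 (6.90). LHCB4.2 (10.6) and ATG8G (5.49) were low on array 2. ATG3 (7.02), AT3G06210 (3.13) and UGT74B1 (7.42) were low on array 3. Among SA arrays, RCA was high on array 18 (11.9).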

How the results depend on the processing

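The spread and range counts, the fits without array 10 as a doubted array, and the replicate-number fits that leave out single arrays, for all or for chloroplast-encoded probe sets, were chosen after seeing the data. The count of 0 changed probe sets held under every alternative except 2 residual principal components, with 2 probe sets, 1 of them at least 2-fold. These components come from the residuals of the same fit and act only on the error, so the 2 may be too many. The count was also 0 with the replicate block, fixed or random. The block changed no other call of the level or list tests between treatments. The other splits of the 18 arrays reached 2.0% of the tested probe sets, and 53 changed at least 2-fold, so that the arrays hold a structure that treatment does not follow. All 100 of 100 splits give at least 0, so they decide nothing about a count of 0. The 1 called list became 0 with an estimated correlation, with the exact permutation of the list mean, and without array 10, and ranged from 0 (without array 10, 11 or 12) to 2 (without array 18, which added the photosynthesis list, lower) when arrays or replicates were left out. With array weights the count was again 1, but the endoplasmic reticulum list, lower, was called (camera, adjusted p = 0.0326) and the SA list was not. The weights were lowest for SA arrays 10, 11 and 12 (0.32, 0.31 and 0.33), on which both lists had their highest means. This fit is therefore no independent test of either list. The SA list was called in 29 of its 35 distinct alternatives, the exact permutation of its mean being among the other 6. All 29 used the preset correlation, so they do not test the assumption on which the call rests. Of 100 splits, which keep no unlabelled condition together, 31 called as many lists, the highest of the others 4, so chance is not excluded by them. The replicate-number count of 97 was 141 without array 10 and ranged from 35 to 141 as arrays were left out. Of 100 reassignments, the real one included, 2 gave as many, the highest other 1062. Such a count was thus rare among the reassignments, but 1 of them gave far more, so chance is not excluded. The large count of that reassignment points again to a structure in the arrays. The interaction count stayed 0 in every alternative run; the splits (100 of 100 with at least 0, the highest other 1) decide nothing there either.

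The count of more variable probe sets (all but 5 of the 403 called) was 239 without the filter and 0 with deviations from the median. With a replicate block the count was 2116, which may overstate the difference, since deviations within sets of 3 arrays are not independent. Without array 10 the count was 0. Leaving out single arrays moved it between 0 and 805: it was 214, 139, 137, 11, 37, 129, 391, 8 and 74 without silwet arrays 1 to 9 in turn, 0 without each of 10, 11 and 12, and 805, 720, 714, 802, 752 and 795 without 13 to 18. The count of 62 probe sets outside the silwet range was 190 on 2 or more SA arrays and 4 without array 10, ranged from 2 (without array 12) to 100 (without array 1) and was 3 without array 11, and 15 of 100 splits gave as many, the highest other 2.59% of the tested probe sets, so chance is not excluded and the arrays again hold a structure. The fall of the range count without array 10, 11 or 12 follows from its construction, since most of these probe sets were outside on just these 3 arrays; the cause of the other shifts was not tested. Of 2788 values of the 88 named probe sets under the alternatives, none passed the threshold. None moved by 1 SD, a bar too wide to show stability. Sign changed for 54 genes, among them AT3G48650 (0.61), GH9C2 (-0.60), AT1G29660 (-0.51), AT4G32870 (0.49) and psbH (-0.44). The 11 single values kept their side of the threshold after quantile normalization. Dim transcripts are limited by the floor, and no detection calls were used.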

Other observations

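The tests of the autophagy genes and of arrays 9 title numbers apart were chosen after the values were seen. Of 24 gene families and groups formed from the symbols, the ATG family (11 probe sets, most of them ATG8 genes, which coat the autophagosome) was called by camera with the preset correlation (adjusted p = 0.000857, 10 of 11 above silwet), and its median log2 difference was 0.08. With an estimated correlation the adjusted p was 0.892. ATG8H differed by 0.69, ATG8B by 0.41, ATG8E by 0.34 and the gene listed as APG8A by 0.28, while ATG3 differed by -0.03; of the 11, 6 (ATG3, ATG8C, ATG8F, ATG8G, APG8H and AT5G66930) took the other sign under some alternative. The mean of the 11 probe sets was 7.52 ± 0.22 (SD, n = 9) with SA and 7.34 ± 0.21 with silwet, and the exact permutation test gave p = 0.0955, so that a rise of this family with SA may be asked of further arrays and is not shown by these. The UGT family (28 probe sets, adjusted p = 0.973), the WRKY family (6, adjusted p = 0.580) and the chloroplast-encoded group (66, adjusted p = 0.664, with a median of -0.06 although the test leaned up) were not called.

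The SA arrays that lay outside the silwet range together were mostly the same ones. Of the 44 probe sets at least 2-fold above every silwet array on 3 or more SA arrays, 42 were so on arrays 10, 11 and 12, and of the 18 below, 16. One by one, SA arrays 10 to 18 had 126, 124, 175, 4, 1, 2, 0, 13 and 0 probe sets at least 2-fold above every silwet array, and 250, 129, 84, 3, 5, 45, 4, 20 and 18 below. Each silwet array against the other 8 had 21, 8, 38, 3, 1, 2, 75, 2 and 0 above and 19, 17, 35, 2, 14, 170, 51, 2 and 13 below, for arrays 1 to 9. Arrays 10, 11 and 12 carry 1 array of each replicate number.

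Arrays of the different treatments resembled each other by their title numbers. After the treatment means were removed, 7 of the 9 SA arrays correlated best, across probe sets, with the silwet array whose title number is 9 lower, at 0.75 for arrays 16 and 7, 0.55 for 18 and 9, 0.54 for 15 and 6 and 0.20 for the weakest, 14 and 5. The mean over the 9 pairs was 0.436, and among the 216 pairings within replicate numbers the exact one-sided p was 0.00926, with 0.440 for the highest other pairing. A condition shared by arrays 9 title numbers apart, such as a harvest time that the labels do not give, is a candidate explanation. In the order of their title numbers, the mean of the SA-inducible list was 7.47, 6.75, 7.16, 6.04, 5.66, 6.35, 5.31, 5.62 and 5.34 on silwet arrays 1 to 9, and 8.98, 8.95, 9.12, 6.31, 6.18, 6.53, 5.55, 5.42 and 5.88 on SA arrays 10 to 18. Each SA array except 17 lay above the silwet array 9 title numbers lower. That comparison was made after the values were seen and was not tested. The shared condition was not used in any fit, since the labels do not state it, and its variation then counts as spread between replicates, so the count of 0 between treatments does not show that no gene responds to SA at some time. Probe sets are not independent replicates, so the correlations describe these arrays only.

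The probe set with the smallest unadjusted p of the treatment comparison among those unnamed here had a log2 signal of 7.13 ± 0.58 with SA and 4.99 ± 1.29 with silwet (SD, n = 9 each), a difference of 2.14 (limma, unadjusted p = 8.72e-05, adjusted p = 1.00).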
